A study of Homo sapiens with 47 samples.

How the data were processed

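Primary endothelial cells had been isolated from human aortic valves with collagenase and grown on gelatin in endothelial cell medium. Per the labels they came from healthy tricuspid, calcified tricuspid or calcified bicuspid valves, and were kept for 7 days with 10 µM XCT790 or with DMSO, renewed on alternating days. RNA was extracted with TRIzol, and libraries were made from total RNA with a kit that amplifies whole transcripts (NuGEN Ovation RNA-Seq System V2). The labels name FastQC, TopHat, SAMtools and Picard without versions, and the genome build hg19. How reads were counted, on which strand, and with which gene annotation is not given in the sources used here. Gene positions are left out because no annotation of that build was at hand.

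The deposited table holds FPKM (fragments per kilobase per 1000000 mapped fragments) by the authors, 1 column for each of the 47 libraries, not on a log scale. It has 15769 genes, of which 899 have no symbol. In 12 symbols a spreadsheet had put a date number, and these were restored from their gene identifiers. Of the identifiers, 14882 were found in GENCODE release 29. After 21 sex-linked genes were taken out, 15748 were left. The authors' own columns of calls were used only for a comparison of calls, and the authors' columns of group means were not used, because few of their values equal the mean of their group's libraries. Those of both XCT790 groups equal the mean of a run of adjacent libraries that begins 1 library early, taking in 1 DMSO library and leaving out 1 treated library. On component 1 each of these lay within the range of the other libraries with its treatment, which gives no sign of a wrong label there. The column for the healthy group equals 1 calcified tricuspid XCT790 library and takes in none of its own 5 libraries. Groups were taken from the labels: 5 groups of 5, 9, 9, 12 and 12 libraries, with replicates numbered from 0. The labels give no batch.

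The files give no depth. It was estimated from 1232 genes with a mean FPKM under 0.3, whose values move in steps of whole reads. With the estimated depths 99.6% of the values in 1173 genes lay within 0.05 of a whole read, against 16.8% with depths shuffled between libraries. The scale in fragments is approximate, while ratios between libraries do not depend on it: the deepest library had 3.57 times the depth of the shallowest. No intervals or limits of detection are given, since these need exact counts.

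Values were analysed as log2(FPKM + 1). Genes with an FPKM of at least 1 in at least 5 libraries were kept (13837). A linear model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3 (trended moderation), and the comparisons were taken as contrasts, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The comparisons were each calcified group with DMSO against healthy cells, both calcified groups against each other, XCT790 against DMSO in each calcified group, each treated group against healthy cells, and the difference between both drug changes. Data were simulated with genes drawn independently, a spread per gene shared by all groups, and changed genes set above their measured level. On these the test recovered 74.2% of genes changed 2-fold in the calcified tricuspid disease comparison and 88.2% in the bicuspid one. In the drug comparisons it recovered 85.1% in tricuspid and 93.8% in bicuspid cells. The real groups differ in spread, so these shares may be too high.

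Genes were named by a rule set before the data were examined: the 10 largest rises and falls among genes that passed, with a mean FPKM of at least 5 in at least 1 group and the same direction whichever library was left out. Where fewer than 10 passed, the 5 smallest p-values in each direction were named as not passing. ESRRA and NOTCH1 were always named, and up to 4 members of a gene list with the smallest p could be described. Gene lists were written before the data were examined, 45 in all, and those with at least 5 measured members were tested with camera (limma) at a preset correlation of 0.01, adjusted over lists. The disease and drug changes were compared over 100 random divisions of the replicate numbers, so that no calcified library entered both, and by an exact sign-flip permutation over replicate numbers. Sharing of control libraries was assessed with 100 simulations of unchanged groups, in which genes were drawn independently.

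The labels do not say that replicate numbers pair libraries across treatments, so this was checked. After group means were removed, libraries with the same number correlated with a median r of 0.38 (range 0.23 to 0.66) across genes in calcified tricuspid cells, against a mean of −0.04 for other numbers, and of 0.25 (0.12 to 0.55) against −0.02 in calcified bicuspid cells. The unpaired fit was the planned one, and a fit with the replicate number as a block was an alternative, in which 8443 and 8527 genes passed in the drug comparisons.

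Settings chosen before the data were examined were another pseudocount (0.1 or 5), no filter or a mean FPKM of at least 5, quantile normalization, a median-of-ratios size factor, TPM, library weights, robust moderation, a fit of only the groups compared, the Wilcoxon rank-sum test, the replicate block alone or with quantile normalization, and leaving out each library. For lists they were an estimated correlation, fry, quantile normalization, a pseudocount of 0.1 and library weights. Chosen after the data were seen were covariates for the mesenchymal marker mean and for log2 depth, and a rescaling without mitochondrially encoded transcripts. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables, depth and figures.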

Results

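RNA was sequenced from primary endothelial cells isolated from human aortic valves and grown in culture. The cells came from healthy valves with the usual tricuspid anatomy, from calcified tricuspid valves and from calcified bicuspid valves, a congenital form with fewer leaflets. Cells from both kinds of calcified valve were grown for 7 days with 10 µM XCT790 or with its control, DMSO, and cells from healthy valves with DMSO. XCT790 is an inverse agonist of the estrogen-related receptor alpha (ERRα, gene ESRRA), a nuclear receptor that drives genes of mitochondrial energy metabolism. The table held FPKM values for 15769 genes in 47 libraries: 5 healthy tricuspid, 9 calcified tricuspid with DMSO, 9 calcified tricuspid with XCT790, 12 calcified bicuspid with DMSO and 12 calcified bicuspid with XCT790. The labels describe the cells as primary cells from patients but do not say whether a library number stands for 1 patient, so p-values measure the spread between libraries. In the main fit this spread was pooled over all 5 groups. The endothelial identity mean had an SD of 1.25 in healthy cells and 0.27 in calcified bicuspid cells with DMSO. Where healthy libraries varied more than the others, p-values against healthy cells may be too small. Changes are given as log2 changes of FPKM + 1 with their standard errors (SE), FPKM levels as mean ± SD over the libraries of a group, and adjusted p-values come from limma unless another test is named. This scale understates the change of genes with low FPKM.

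The files give no depth, but low FPKM values moved in whole-read steps and gave an approximate depth of 2.62 to 9.38 per library, in units of 1000000 fragments. Libraries with XCT790 were deeper than the DMSO library of the same number in 8 of 9 tricuspid and 12 of 12 bicuspid pairs. In the same units the approximate depth was 5.23 ± 0.57 in healthy tricuspid cells (SD, n = 5), 5.23 ± 0.71 in calcified tricuspid cells with DMSO (n = 9) and 7.90 ± 1.18 with XCT790 (n = 9), and 4.49 ± 0.93 in calcified bicuspid cells with DMSO (n = 12) and 7.16 ± 1.59 with XCT790 (n = 12). Between 11685 and 12648 genes reached an FPKM of 1 in each library, and the 13837 genes that did so in at least 5 libraries were tested. The first principal component took up 41.5% of the variance and parted the libraries by drug. All 26 DMSO libraries lay between −44.3 and −11.4 on it, and 20 of the 21 XCT790 libraries between 28.2 and 63.2, with 1 calcified bicuspid XCT790 library at −12.0. On the second component (15.9% of the variance), healthy libraries averaged −44.5 ± 38.5, calcified tricuspid DMSO libraries 1.5 ± 32.7 and calcified bicuspid DMSO libraries 10.3 ± 12.6.

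**Figure D1:**
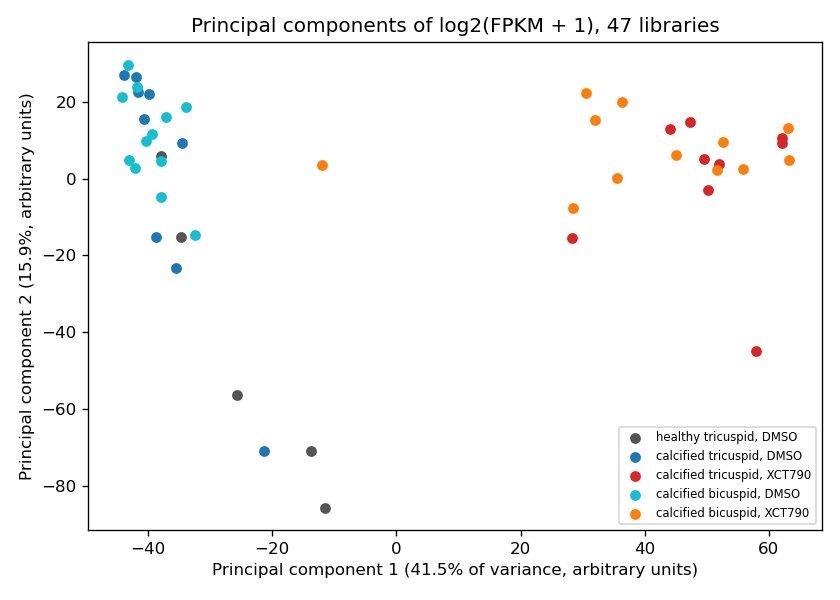
Each point is 1 of the 47 libraries, placed by its score on principal component 1 (x axis, 41.5% of the variance) and 2 (y axis, 15.9%) of log2(FPKM + 1), in arbitrary units, with a colour per group. All but 1 of the 21 libraries with XCT790 lie at 28.2 or above on component 1, and every DMSO library lies at −11.4 or below.

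The first comparison asked how cells of calcified tricuspid valves differ from cells of healthy tricuspid valves without the drug. Endothelial genes were among the largest rises in the calcified group. VWF (ENSG00000110799), the carrier of clotting factor VIII stored in endothelial granules, averaged 243 ± 135 FPKM (SD, n = 9) against 67.4 ± 59.3 in healthy cells (n = 5), a log2 change of 2.45 ± 0.80, adjusted p = 0.042. The healthy libraries differed widely, with VWF at 13.4, 3.16, 99.2, 77.1 and 144 FPKM in replicates 0, 1, 2, 3 and 4. Calcified libraries ranged from 35.8 to 480 FPKM, so only healthy replicates 0 and 1 lay below that range. CLU, an extracellular chaperone, rose from 39.1 ± 34.6 to 162 ± 89.2 FPKM (2.33 ± 0.53, adjusted p = 0.0098), and the fatty acid binding protein FABP4 rose by 2.25 ± 0.70. The other genes with the largest rises were AIF1L (2.35 ± 0.58), MAN1C1 (2.18 ± 0.55), MINDY4 (2.0 ± 0.44), FLRT2 (1.95 ± 0.42), PKHD1L1 (1.93 ± 0.58), CAVIN2 (1.90 ± 0.52) and GALNT15 (1.88 ± 0.60). IGFBP5, a secreted binding protein of insulin-like growth factors, averaged 68.7 ± 48.2 FPKM in healthy cells and 1.07 ± 1.83 in calcified ones (−4.94 ± 0.52, adjusted p = 1.52e-08). HAPLN1, which links hyaluronan to proteoglycans in the matrix, fell from 10.9 ± 2.89 to 0.234 ± 0.265 FPKM (−3.26 ± 0.27, adjusted p = 1.99e-11). PDGFRA, the platelet-derived growth factor receptor of mesenchymal cells (−3.04 ± 0.71), the chemokine CXCL6 (−2.96 ± 0.63), complement C3 (−2.95 ± 0.68), RAB27B (−2.90 ± 0.72), CADM3 (−2.82 ± 0.83), GALNT5 (−2.79 ± 0.77), the EGF receptor ligand AREG (−2.79 ± 0.52) and the growth factor IGF2 (−2.58 ± 0.84) also fell. NOTCH1 (ENSG00000148400), a receptor whose loss is known to cause valve calcification, averaged 18.7 ± 5.72 against 10.7 ± 6.66 FPKM (0.87 ± 0.26, adjusted p = 0.0316). ESRRA (ENSG00000173153) averaged 7.22 ± 1.01 against 7.2 ± 1.62 FPKM and did not pass the test (adjusted p = 0.964).

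By gene list in the same comparison, 11 of 29 measured genes of endothelial identity rose and none fell (25 and 0 when adjusted over the list alone), with a median log2 change of 1.11. With quantile normalization 5 of these genes rose, and 7 with a median-of-ratios size factor. The 11 in the main fit included EMCN (1.84 ± 0.44), TIE1 (1.53 ± 0.40), ERG (1.42 ± 0.38) and CLDN5 (1.43 ± 0.39). The list stood above other genes by camera (adjusted p = 5.4e-08), but not with an estimated correlation (adjusted p = 0.36 with an estimated correlation). Of 30 cell cycle genes 10 rose, among them CCNE2 (0.84 ± 0.21) and CDC20 (0.80 ± 0.22), and 1 fell (19 and 1 adjusted over the list alone). Quantile normalization gave 6 cell cycle genes higher, and a median-of-ratios size factor 7. Camera on cell cycle gave adjusted p = 4.5e-06, and adjusted p = 0.36 with an estimated correlation. Of 27 NF-kB and inflammatory genes 8 fell and none rose (10 and 0 adjusted over the list alone; camera adjusted p = 1.0e-08, and adjusted p = 0.36 with an estimated correlation), including the cytokine IL1B (−2.06 ± 0.45) and the chemokine CXCL1 (−2.03 ± 0.49). Of 23 mesenchymal and interstitial cell genes FAP (−1.70 ± 0.36) and PDGFRA fell (5 adjusted over the list alone), with a list median of −0.90. Camera on mesenchymal genes gave adjusted p = 6.9e-07, and adjusted p = 0.36 with an estimated correlation. TPM1 (−1.06 ± 0.31) and TPM2 (−1.84 ± 0.58) fell among 12 smooth muscle and myofibroblast genes (2 adjusted over the list alone; camera adjusted p = 0.0017, and 0.36 as the adjusted p with an estimated correlation). Of 31 extracellular matrix genes 4 fell, with TIMP1 (−1.84 ± 0.55) and ADAMTS1 (−1.77 ± 0.47) among them, and 1 rose (5 and 1 adjusted over the list alone). Camera on matrix genes gave adjusted p = 0.0029, and adjusted p = 0.36 with an estimated correlation. Glycolysis had 3 lower genes of 21, led by LDHA (−0.75 ± 0.19) (3 adjusted over the list alone). Camera on glycolysis gave adjusted p = 0.00040, and adjusted p = 0.36 with an estimated correlation. Of the 21 osteogenic and calcification genes OMD (−1.36 ± 0.36) and TNFRSF11B (−1.45 ± 0.49) fell and none rose (4 and 1 adjusted over the list alone). Camera on osteogenic genes gave adjusted p = 0.029, and adjusted p = 0.36 with an estimated correlation. The 74 oxidative phosphorylation genes had a median of −0.17 (camera adjusted p = 2.2e-06). No list was called in this comparison with an estimated correlation.

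Mesenchymal markers moved with the group. Their mean log2(FPKM + 1) per library was 4.96 ± 0.98 in healthy cells (SD, n = 5) and 3.76 ± 1.18 in calcified tricuspid cells with DMSO (n = 9), while the endothelial identity mean was 4.49 ± 1.25 and 5.65 ± 0.73. By limma, 1387 of 13837 genes passed in the calcified tricuspid comparison, 951 higher and 436 lower, of which 414 changed by at least 2-fold. The share of higher genes was 68.6%, but 50.4% after quantile normalization and 47.1% with a median-of-ratios size factor. The count was 39 without healthy replicate 1 and 2909 without calcified tricuspid DMSO replicate 1, 81 with the mesenchymal mean as a covariate, 2 when only these groups were fitted, and 0 by the Wilcoxon rank-sum test, where 3829 genes had an unadjusted limma p under 0.05.

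The next comparison set calcified bicuspid cells against the same healthy tricuspid cells, so disease and anatomy could not be separated in it. Endothelial genes were again among the largest rises. CD34, a sialomucin of vascular endothelium, averaged 200.1 ± 106 FPKM (SD, n = 12) against 56 ± 49.5 in healthy cells (n = 5), a log2 change of 2.17 ± 0.76, adjusted p = 0.0325. Its FPKM was 16.1, 5.67, 112, 42.1 and 104 in healthy replicates 0, 1, 2, 3 and 4, against 19.1 to 345 in calcified bicuspid libraries. Again only healthy replicates 0 and 1 lay below the calcified range. The endothelial sialomucin EMCN averaged 201 ± 44.4 against 68.3 ± 55.6 FPKM (2.13 ± 0.42, adjusted p = 0.000899), and GJA4, a gap junction protein of endothelium, rose by 2.14 ± 0.59. VWF rose by 2.14 ± 0.76, AIF1L by 2.24 ± 0.56, MAN1C1 by 2.17 ± 0.52, CLU by 2.16 ± 0.51, CAVIN2 by 2.08 ± 0.49, CYYR1 by 2.04 ± 0.46 and the antisense transcript XXYLT1-AS2 by 2.12 ± 0.48. Reads of an antisense transcript and its partner gene may not be told apart, since the strand of counting is not given in the sources used here. IGFBP5 fell to 0.80 ± 0.787 FPKM (−4.92 ± 0.50, adjusted p = 4.02e-09) and HAPLN1 to 0.842 ± 2.33 FPKM (−3.08 ± 0.26, adjusted p = 2.64e-11). DCN, the matrix proteoglycan decorin, averaged 11.7 ± 11.3 against 255 ± 278 FPKM (−3.62 ± 1.10, adjusted p = 0.0151), and HSD11B1, which activates cortisone to cortisol, averaged 0.267 ± 0.338 against 70.0 ± 94.8 FPKM (−3.74 ± 0.91, adjusted p = 0.00333). CADM3 (−4.04 ± 0.79), PDGFRA (−3.79 ± 0.68), RAB27B (−3.45 ± 0.69), AREG (−3.08 ± 0.50), CXCL6 (−3.02 ± 0.60) and C3 (−2.96 ± 0.65) were the other genes with the largest falls. NOTCH1 averaged 21.3 ± 4.65 against 10.7 ± 6.66 FPKM (1.09 ± 0.25, adjusted p = 0.00225), and ESRRA 6.8 ± 1.26 against 7.2 ± 1.62 FPKM (adjusted p = 0.789).

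In calcified bicuspid cells 24 of 29 endothelial identity genes rose and none fell (26 and 0 adjusted over the list alone), with a median of 1.44. TIE1 (1.88 ± 0.38), ERG (1.73 ± 0.37) and SOX7 (1.37 ± 0.31) were among them. Camera on endothelial identity gave adjusted p = 6.6e-10, and adjusted p = 0.43 with an estimated correlation. Of 13 endothelial transcription regulators 8 rose and none fell (10 and 0 adjusted over the list alone), including SMAD1 (1.34 ± 0.28). Camera on endothelial regulators gave adjusted p = 0.0017, and adjusted p = 0.43 with an estimated correlation. Cell cycle genes were higher in 26 of 30 and lower in 1 (27 and 1 adjusted over the list alone), with CDC20 (1.15 ± 0.21), KIF11 (0.80 ± 0.16) and AURKB (0.68 ± 0.14) among the risers. Camera on cell cycle gave adjusted p = 5.5e-10, and adjusted p = 0.43 with an estimated correlation. Of 23 mesenchymal and interstitial cell genes 7 fell, FAP (−1.83 ± 0.35) and TWIST2 (−0.88 ± 0.27) among them, and none rose (12 and 1 adjusted over the list alone). Camera on mesenchymal genes gave adjusted p = 3.0e-07, and adjusted p = 0.43 with an estimated correlation. Of 27 NF-kB and inflammatory genes 6 fell, including CCL20 (−2.54 ± 0.64) and LIF (−1.06 ± 0.24), and none rose (10 and 1 adjusted over the list alone). Camera on NF-kB genes gave adjusted p = 1.1e-05, and adjusted p = 0.43 with an estimated correlation. Glycolysis had 7 lower genes of 21, LDHA (−0.72 ± 0.18) and HK2 (−0.61 ± 0.18) among them (8 and 1 higher adjusted over the list alone). Camera on glycolysis gave adjusted p = 0.00052, and adjusted p = 0.43 with an estimated correlation. Of 21 osteogenic and calcification genes 6 fell, including RUNX2, the master regulator of bone formation (−1.85 ± 0.55), and SOX9 (−1.90 ± 0.55), and 2 rose, BMP6 (1.24 ± 0.37) among them (6 and 3 adjusted over the list alone). Camera on osteogenic genes gave adjusted p = 0.049, and adjusted p = 0.44 with an estimated correlation. The 74 oxidative phosphorylation genes had a median of −0.19 (camera adjusted p = 3.7e-06). With an estimated correlation no list was called in this comparison.

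The mesenchymal marker mean was 3.62 ± 0.77 in calcified bicuspid cells with DMSO (SD, n = 12) against 4.96 ± 0.98 in healthy cells (n = 5), and the endothelial identity mean 5.91 ± 0.27 against 4.49 ± 1.25. By limma 3336 of 13837 genes passed, 2317 higher and 1019 lower, of which 740 changed by at least 2-fold. The higher genes made up 69.5% of these, but 51.8% after quantile normalization and 48.1% with a median-of-ratios size factor. The count was 836 with the mesenchymal mean as a covariate, 730 by the Wilcoxon rank-sum test, and 991, 1561 and 2182 without healthy replicates 1, 0 and 3.

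Both disease comparisons shared many called genes: 904 were higher in both and 419 lower in both, where lists drawn independently would share 159 and 32. Across the 13837 genes, which are not independent replicates, the changes correlated with r = 0.948 and had a covariance of 0.218. Both comparisons used the same healthy libraries, which by itself raises the number of shared calls. The counts for independent lists do not allow for this, and no count with that sharing was simulated. Unchanged groups simulated with shared healthy libraries, genes being drawn independently, gave a mean r of 0.743 and a mean covariance of 0.051. The difference in covariance was 0.168. Real genes vary together, so the covariance that sharing gives by chance can lie far from the simulated mean. The difference alone therefore does not show agreement beyond the sharing. With the healthy libraries split into 2 and 3, the median over 20 splits was r = 0.694 (range 0.189 to 0.807) with a covariance of 0.181.

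The direct comparison of both calcified groups with DMSO asked whether anatomy set them apart. No gene passed by limma (354 of 13837 had an unadjusted p under 0.05), and none passed by the Wilcoxon rank-sum test. The genes with the smallest p, none of which passed, were RELT (0.34), MRPL35P3 (0.95), PARPBP (0.43), TLNRD1 (0.43) and CIB2 (0.47) on the higher side in bicuspid cells, and CLEC10A (−0.69), SNORD102 (−1.18), MELTF-AS1 (−0.46), RIOX1 (−0.36) and PTGR2 (−0.53) on the lower side. Their unadjusted p ranged from 0.000191 (RELT) to 0.00308 (PTGR2), and the adjusted p was 1 for each. NOTCH1 averaged 21.3 ± 4.65 FPKM in bicuspid cells (n = 12) and 18.7 ± 5.72 in tricuspid cells (n = 9). With no single member passing, adjusted over all genes or over the list alone, camera placed 5 lists apart from other genes. In bicuspid cells the lists of cell cycle (median 0.20, adjusted p = 2.5e-12), endothelial identity (0.34, 9.2e-05) and endothelial transcription regulators (0.24, 0.0062) were higher, and those of cholesterol synthesis (−0.15, 1.7e-05) and ribosomal proteins (−0.05, 0.013) lower. None was called with an estimated correlation, where the adjusted p with an estimated correlation was 0.68 for cell cycle, cholesterol synthesis and endothelial transcription regulators, 0.86 for endothelial identity and 0.92 for ribosomal proteins. On simulated data for this comparison, with a spread shared by all groups, the same test recovered 72.2% of genes changed 1.5-fold and 90.6% of genes changed 2-fold. These shares may be too high.

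XCT790 was then compared with DMSO in calcified tricuspid cells, to ask what the drug does to them. It was the only treatment and was given at 10 µM alone. Effects through ERRα can therefore not be told apart from other effects of the drug. Genes of amino acid synthesis and the integrated stress response were among the largest rises. ASNS, asparagine synthetase, averaged 95 ± 17.3 FPKM with XCT790 (SD, n = 9) and 5.95 ± 3.68 with DMSO (n = 9), a log2 change of 3.93 ± 0.23, adjusted p = 1.18e-18. PSAT1 (3.78 ± 0.24, adjusted p = 2.00e-17) and PHGDH (3.83 ± 0.34, adjusted p = 7.67e-13), enzymes of serine synthesis, and TRIB3, a pseudokinase induced by ATF4 (3.69 ± 0.18, adjusted p = 1.07e-20), rose alongside it. LAMP3, a lysosomal membrane protein, rose from 1.65 ± 0.851 to 75.9 ± 31.7 FPKM (4.77 ± 0.32, adjusted p = 6.37e-17), and IGFBP3 from 22.1 ± 17 to 456 ± 136 FPKM (4.59 ± 0.46, adjusted p = 2.83e-11). STC2 (4.53 ± 0.43), BEX2 (3.94 ± 0.35), CYP1B1 (3.89 ± 0.63) and IL13RA2 (3.64 ± 0.42) completed the largest rises. Endothelial genes were among the largest falls. VWF averaged 4.36 ± 4.96 FPKM with XCT790 against 243 ± 135 with DMSO (−5.64 ± 0.67, adjusted p = 2.23e-09), CD34 3.27 ± 5.27 against 168 ± 101 FPKM (−5.78 ± 0.67, adjusted p = 1.25e-09), and the hyaluronan receptor LYVE1 3.71 ± 6.31 against 156 ± 61.5 FPKM (−5.74 ± 0.59, adjusted p = 5.93e-11). GJA4 (−5.51 ± 0.52), complement C7 (−5.33 ± 0.54), the matrix protein periostin, POSTN (−5.20 ± 0.60), the ribonucleotide reductase subunit RRM2 (−4.77 ± 0.21), P-selectin, SELP (−4.65 ± 0.64), GIMAP4 (−4.51 ± 0.48) and the mitochondrially encoded MT-CO2 (−4.38 ± 0.73) fell as well. The transcript of the drug's target, ESRRA, averaged 14 ± 3.63 against 7.22 ± 1.01 FPKM (0.83 ± 0.14, adjusted p = 5.12e-06), and NOTCH1 15.2 ± 6.03 against 18.7 ± 5.72 FPKM (adjusted p = 0.311).

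All 26 measured genes of the integrated stress response rose with XCT790 in calcified tricuspid cells (26 adjusted over the list alone), with a median of 2.59. Camera on the stress response gave adjusted p = 1.7e-20, and adjusted p = 0.0052 with an estimated correlation. MTHFD2 (3.03 ± 0.18) and SLC3A2 (2.43 ± 0.15) were among them. Of 12 amino acid and one-carbon transport genes 11 rose and none fell (11 and 0 adjusted over the list alone), including SLC1A5 (1.78 ± 0.12) and SLC1A4 (2.27 ± 0.16). Camera on amino acid transport gave adjusted p = 3.4e-11, and adjusted p = 0.0052 with an estimated correlation. Of 30 cell cycle genes 28 fell and none rose (28 and 0 adjusted over the list alone), with a median of −2.26. MKI67, a marker of proliferating cells, went from 24.3 ± 6.01 to 0.446 ± 0.32 FPKM (−4.12 ± 0.19, adjusted p = 2.24e-21), and BIRC5 (−3.89 ± 0.19) and AURKB (−2.56 ± 0.12) fell too. Camera on cell cycle gave adjusted p = 3.8e-31, and adjusted p = 0.0052 with an estimated correlation. Among 8 calcification inhibitors 6 fell and none rose (6 and 0 adjusted over the list alone), MGP, which binds calcium in the matrix (−3.66 ± 0.56), and NT5E (−0.93 ± 0.15) among them. Camera on calcification inhibitors gave adjusted p = 0.0047, and adjusted p = 0.033 with an estimated correlation. With the replicate block and an estimated correlation none of these 4 lists was called, with adjusted p of 0.068 for the integrated stress response, the cell cycle and the calcification inhibitors and 0.11 for amino acid and one-carbon transport.

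Other lists also moved in calcified tricuspid cells by camera but not with an estimated correlation. Endothelial identity had 23 of 29 genes lower and none higher (23 and 0 adjusted over the list alone), with a median of −1.30 and SOX18 among the genes that fell (−3.44 ± 0.38). Camera on endothelial identity gave adjusted p = 1.2e-07, and adjusted p = 0.36 with an estimated correlation. All 13 mitochondrially encoded transcripts fell (13 adjusted over the list alone), with a median of −3.44. With depth as a covariate 9 of 13 were still called lower and the median was −1.63. MT-CO1 averaged 1035 ± 1418 against 10036 ± 1417 FPKM (−4.10 ± 0.66, adjusted p = 1.40e-06), and MT-CYB and MT-CO3 changed by −4.05 ± 0.60 and −3.88 ± 0.55. Camera on mitochondrial transcripts gave adjusted p = 2.4e-07, and adjusted p = 0.32 with an estimated correlation. Ribosomal protein genes rose in 58 of 73 and fell in 1 (59 and 1 adjusted over the list alone), with a median of 0.56 and RPL12 (0.97 ± 0.13) among the risers. Camera on ribosomal proteins gave adjusted p = 3.5e-07, and adjusted p = 0.52 with an estimated correlation. Of 20 NRF2 oxidative stress genes 16 rose and none fell (16 and 1 adjusted over the list alone), including the cystine transporter SLC7A11 (3.07 ± 0.25) and TXNRD1 (2.24 ± 0.20). Camera on NRF2 genes gave adjusted p = 9.0e-07, and adjusted p = 0.13 with an estimated correlation. Extracellular matrix genes fell in 21 of 31 and rose in 1 (21 and 1 adjusted over the list alone), with SPARC (−2.48 ± 0.26) and NID1 (−1.72 ± 0.20) among them. Camera on matrix genes gave adjusted p = 3.4e-06, and adjusted p = 0.15 with an estimated correlation. Cholesterol synthesis had 15 lower and 1 higher gene of 24 (15 and 1 adjusted over the list alone). Camera on cholesterol synthesis gave adjusted p = 2.0e-05, and adjusted p = 0.36 with an estimated correlation. Of 10 genes of the aryl hydrocarbon receptor response 7 rose and none fell (7 and 0 adjusted over the list alone), TIPARP (2.47 ± 0.14) and CYP1A1 (3.02 ± 0.46) among them. Camera on the xenobiotic response gave adjusted p = 0.0040, and adjusted p = 0.071 with an estimated correlation. Of 23 mesenchymal and interstitial cell genes 9 fell and none rose (8 and 0 adjusted over the list alone), including COL3A1 (−4.21 ± 0.62). Camera on mesenchymal genes gave adjusted p = 0.0050, and adjusted p = 0.49 with an estimated correlation. Of 21 osteogenic and calcification genes 10 fell and 2 rose (10 and 2 adjusted over the list alone), with a median of −0.66. Camera on osteogenic genes gave adjusted p = 0.0050, and adjusted p = 0.21 with an estimated correlation.

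By limma 7219 of 13837 genes passed with XCT790 in calcified tricuspid cells, 4256 higher and 2963 lower, of which 698 rose and 941 fell by at least 2-fold. The higher genes were 59.0% of these, but 44.9% when FPKM was rescaled to the sum without mitochondrially encoded transcripts, a rescaling that moved the median of all genes from 0.085 to −0.035. Mitochondrially encoded transcripts took up 16.2% ± 2.58 of the FPKM sum with DMSO and 3.06% ± 2.47 with XCT790 (SD, n = 9 each). The share was lower with XCT790 in 9 of 9 pairs, by a mean of −13.1 ± 3.73 percentage points (exact two-sided sign-flip permutation test, p = 0.00391, the smallest it can give). Depth moved with the drug too, being higher with XCT790 in 8 of 9 pairs (mean ratio 1.55), and the mesenchymal marker mean went from 3.76 ± 1.18 to 2.53 ± 0.94.

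**Figure D2:**
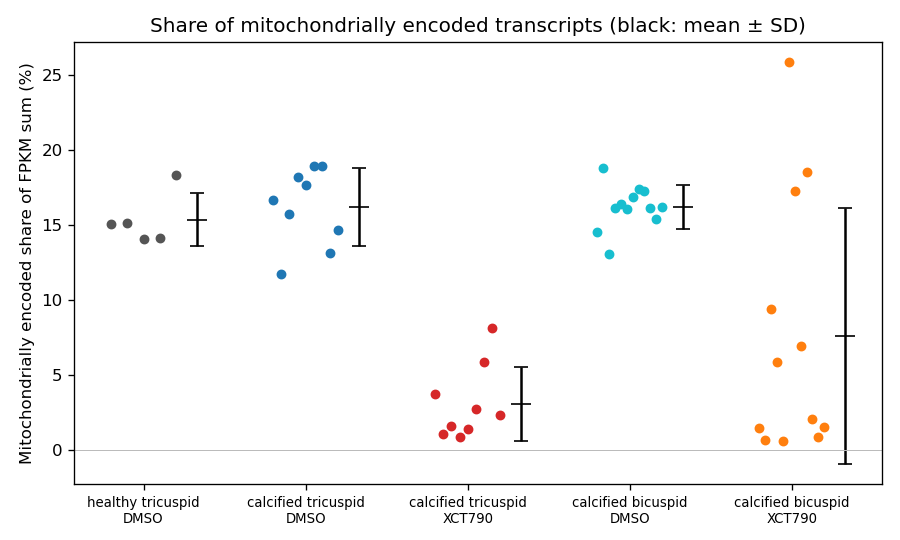
Share of the FPKM sum taken by mitochondrially encoded transcripts (y axis, percent) in each library, by group (x axis), with 1 point per library and bars at the group mean ± SD. The 3 DMSO groups average 15.4%, 16.2% and 16.2%, and the XCT790 groups 3.06% (calcified tricuspid) and 7.57% (calcified bicuspid, range 0.55% to 25.9%).

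In calcified bicuspid cells XCT790 was likewise compared with DMSO. ASNS averaged 97.4 ± 24.1 FPKM with XCT790 (SD, n = 12) against 5.54 ± 2.35 with DMSO (n = 12), a log2 change of 3.95 ± 0.20, adjusted p = 2.23e-21. The collagenase MMP1 rose from 185 ± 169 to 3089 ± 1889.5 FPKM (4.24 ± 0.84, adjusted p = 4.35e-05), LAMP3 from 2.08 ± 1.16 to 60.7 ± 30.9 FPKM (4.20 ± 0.27, adjusted p = 2.12e-17), and PHGDH (4.14 ± 0.29), PSAT1 (3.99 ± 0.21), IGFBP3 (3.70 ± 0.40), BEX2 (3.66 ± 0.30), CBS, which makes cystathionine from homocysteine (3.46 ± 0.27), STC2 (3.46 ± 0.37) and ADM2 (3.39 ± 0.19) rose. GJA4 averaged 2.43 ± 7.83 against 95.7 ± 43.7 FPKM (−5.80 ± 0.45, adjusted p = 1.03e-14), and CD34 11 ± 25.1 against 200.1 ± 106 FPKM (−5.26 ± 0.58, adjusted p = 2.86e-10). VWF (−4.68 ± 0.58), LYVE1 (−4.67 ± 0.51), POSTN (−4.76 ± 0.52), C7 (−4.50 ± 0.46), SELP (−4.45 ± 0.55) and the cycle genes RRM2 (−4.86 ± 0.18), MKI67 (−4.46 ± 0.17) and KIF20A (−4.22 ± 0.17) fell. ESRRA rose from 6.8 ± 1.26 to 12.9 ± 3.39 FPKM (0.80 ± 0.13, adjusted p = 6.47e-07), and NOTCH1 fell from 21.3 ± 4.65 to 13.4 ± 3.78 FPKM (−0.64 ± 0.19, adjusted p = 0.00502). The treated library at −12.0 on component 1 stood apart: among 38 genes named for this comparison it lay between all DMSO and all other treated libraries for 19 and within the DMSO range for 14. Without it the treated mean moved by over 1.5 times for 12 of the 38, CD34 averaging 3.91 ± 5.79 and GJA4 0.172 ± 0.181 FPKM (SD, n = 11), and the log2 changes of CD34, GJA4 and VWF were −5.67, −6.18 and −5.07.

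The lists moved as follows in calcified bicuspid cells. All 26 integrated stress response genes rose (26 adjusted over the list alone), with a median of 2.49, MTHFD2 (2.99 ± 0.15) and TRIB3 (3.27 ± 0.16) among them. Camera on the stress response gave adjusted p = 5.2e-23, and adjusted p = 0.0022 with an estimated correlation. All 30 cell cycle genes fell (30 adjusted over the list alone), with a median of −2.53, AURKB (−2.74 ± 0.11) and BIRC5 (−3.98 ± 0.16) among them. Camera on cell cycle gave adjusted p = 6.4e-36, and adjusted p = 0.0022 with an estimated correlation. All 12 amino acid and one-carbon transport genes rose (12 adjusted over the list alone), SLC1A5 (1.64 ± 0.11) and SLC3A2 (2.23 ± 0.13) among them. Camera on amino acid transport gave adjusted p = 1.2e-12, and adjusted p = 0.0022 with an estimated correlation. Of 10 genes of the aryl hydrocarbon receptor response 7 rose and none fell (8 and 0 adjusted over the list alone), ALDH3A1 (2.45 ± 0.18) among them. Camera on the xenobiotic response gave adjusted p = 0.0022, and adjusted p = 0.049 with an estimated correlation. Of 8 calcification inhibitors 6 fell, including the fibrillin FBN1 (−1.82 ± 0.24) and MGP (−3.08 ± 0.49), and 1 rose (6 and 1 adjusted over the list alone). Camera on calcification inhibitors gave adjusted p = 0.0062, and adjusted p = 0.049 with an estimated correlation. With the replicate block and an estimated correlation only the cell cycle list was called (adjusted p = 0.045), while the adjusted p was 0.055 for the integrated stress response, 0.085 for amino acid transport and for the calcification inhibitors, and 0.11 for the aryl hydrocarbon receptor response.

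Further lists in calcified bicuspid cells were called by camera but not with an estimated correlation. Ribosomal protein genes rose in 64 of 73 and none fell (65 and 0 adjusted over the list alone), with RPS27 (1.33 ± 0.15) among them. Camera on ribosomal proteins gave adjusted p = 6.7e-13, and adjusted p = 0.35 with an estimated correlation. NRF2 oxidative stress genes rose in 16 of 20 and none fell (16 and 0 adjusted over the list alone), GCLM (1.66 ± 0.14) and SLC7A11 (2.91 ± 0.22) among them. Camera on NRF2 genes gave adjusted p = 1.2e-08, and adjusted p = 0.051 with an estimated correlation. Endothelial identity genes fell in 23 of 29 and none rose (23 and 0 adjusted over the list alone), with a median of −1.19 and SOX18 (−3.17 ± 0.33) among them. Camera on endothelial identity gave adjusted p = 2.4e-07, and adjusted p = 0.35 with an estimated correlation. Extracellular matrix genes fell in 22 of 31 and 1 rose (23 and 1 adjusted over the list alone), LOXL2 (−1.92 ± 0.25) among those lower. Camera on matrix genes gave adjusted p = 2.7e-06, and adjusted p = 0.14 with an estimated correlation. All 13 mitochondrially encoded transcripts fell (13 adjusted over the list alone), with a median of −2.62, MT-CO3 going from 3921 ± 489.5 to 1047 ± 1300.5 FPKM (−3.16 ± 0.48). With depth as a covariate 1 of 13 was still called lower and the median was −0.53, and the mean of the list was higher with XCT790 in 2 of 12 pairs. Camera on mitochondrial transcripts gave adjusted p = 1.4e-05, and adjusted p = 0.35 with an estimated correlation. Cholesterol synthesis genes fell in 15 of 24 and 1 rose (15 and 1 adjusted over the list alone). Camera on cholesterol synthesis gave adjusted p = 0.00017, and adjusted p = 0.35 with an estimated correlation. Interferon response genes fell in 15 of 28 and 2 rose (17 and 2 adjusted over the list alone), OAS2 (−1.82 ± 0.30) among those lower. Camera on interferon response gave adjusted p = 0.0020, and adjusted p = 0.46 with an estimated correlation. Osteogenic and calcification genes fell in 9 of 21 and 3 rose (9 and 3 adjusted over the list alone), with a median of −0.50. Camera on osteogenic genes gave adjusted p = 0.0091, and adjusted p = 0.26 with an estimated correlation.

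By limma 7337 of 13837 genes passed in calcified bicuspid cells, 4059 higher and 3278 lower, of which 512 rose and 849 fell by at least 2-fold. The share of higher genes was 55.3%, but 36.4% when FPKM was rescaled to the sum without mitochondrially encoded transcripts, which moved the median of all genes from 0.043 to −0.097. Their share of the FPKM sum was 16.2% ± 1.45 with DMSO and 7.57% ± 8.55 with XCT790 (SD, n = 12 each), lower with XCT790 in 9 of 12 pairs by a mean of −8.63 ± 8.60 percentage points (permutation test of all sign flips, two-sided, p = 0.00781). Depth was higher with XCT790 in 12 of 12 pairs (mean ratio 1.64), and the mesenchymal marker mean went from 3.62 ± 0.77 to 2.42 ± 0.68.

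**Figure D3:**
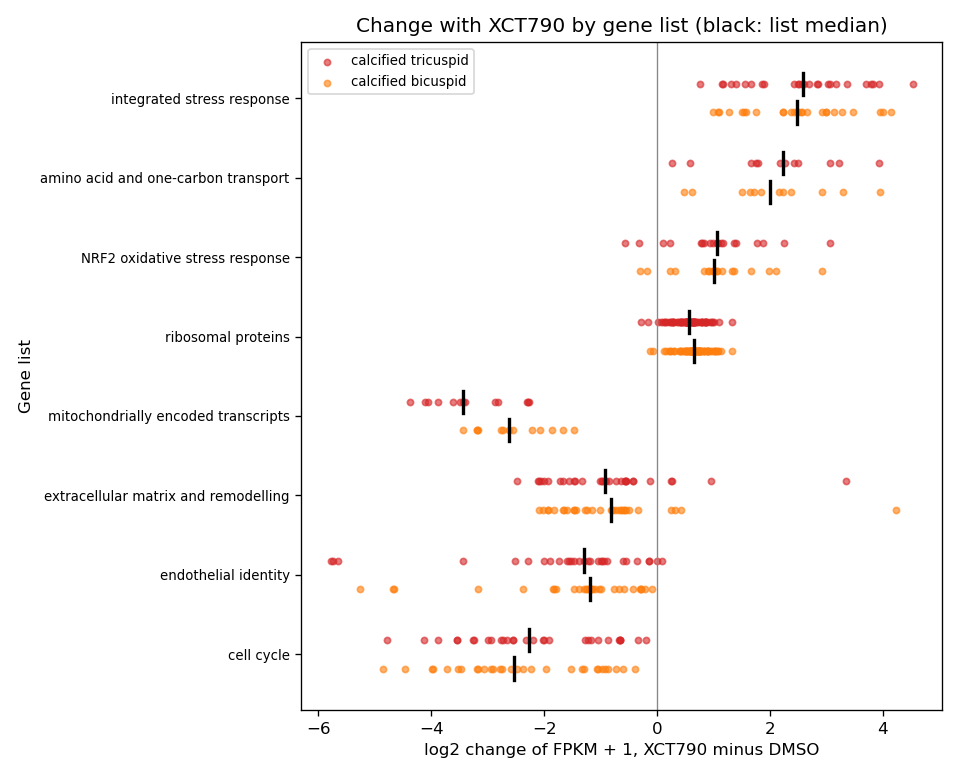
Log2 change with XCT790 (x axis, XCT790 minus DMSO) for each measured member of 8 gene lists (y axis), with 1 point per gene, calcified tricuspid above calcified bicuspid in each row and a bar at the list median. The integrated stress response lies above 0 in both (medians 2.59 and 2.49), and the cell cycle below 0 (medians −2.26 and −2.53).

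The drug changes in both kinds of calcified valve were then set against each other. Across the 13837 genes, which are not independent replicates, they correlated with r = 0.964 (Spearman's rho 0.942), with a slope of bicuspid on tricuspid of 0.877. No library was shared between them. In total 3548 genes rose in both and 2641 fell in both, where independent lists would share 1248 and 702, and 2 genes passed in both with opposite directions. The test of the difference between both drug changes called no gene by limma (300 had an unadjusted p under 0.05), and no Wilcoxon test was run for it. The smallest p on the side of a higher change in bicuspid cells were those of LINC01985 (1.18), NUDT7 (0.77), SDHD (0.28), MLLT10P1 (1.15) and TCEAL1 (0.41). On the lower side were E2F3 (−0.36), CIB2 (−0.63), HINFP (−0.54), CTNNBL1 (−0.45) and MAP1S (−0.37). None of these 10 passed (adjusted p = 1), and E2F3 had the smallest unadjusted p (0.000821). The difference in the drug change was −0.03 ± 0.19 for ESRRA and −0.36 ± 0.30 for NOTCH1 (both adjusted p = 1). On simulated data with a spread shared by all groups, this test recovered 66.1% of genes whose change differed 2-fold and 97.1% of those that differed 4-fold. These shares may be too high.

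Treated calcified cells were also compared with healthy cells, to ask how far they lay from them. In calcified tricuspid cells with XCT790 (n = 9) against healthy cells with DMSO (n = 5), LAMP3 averaged 75.9 ± 31.7 against 1.42 ± 0.677 FPKM (SD, 4.88 ± 0.37, adjusted p = 2.94e-14), and GDF15, a secreted stress cytokine, 600.2 ± 202 against 39.6 ± 27.3 FPKM (4.07 ± 0.36, adjusted p = 1.26e-12). TRIB3 (4.21 ± 0.22), BEX2 (4.16 ± 0.41), PSAT1 (4.13 ± 0.29), PHGDH (3.83 ± 0.40), ASNS (3.73 ± 0.27), NIBAN1 (3.63 ± 0.32), CLGN (3.44 ± 0.56) and CHAC1 (3.40 ± 0.25) were the other largest rises. The fibrillar collagen COL1A1 averaged 12.9 ± 18.2 against 848 ± 769 FPKM (−6.35 ± 1.46, adjusted p = 0.000361), and COL1A2 (−6.27 ± 1.22), COL3A1 (−5.82 ± 0.74), CXCL6 (−5.06 ± 0.63), DCN (−4.65 ± 1.16), IGFBP5 (−4.51 ± 0.52), CADM3 (−4.39 ± 0.83), MT-CO1 (−4.25 ± 0.78) and ITGBL1 (−4.21 ± 0.64) were lower. By limma 6824 genes passed, 4559 higher and 2265 lower. The higher genes were 66.8%, but 49.4% with a median-of-ratios size factor, which moved the median of all genes from 0.15 to −0.004, and 55.9% when rescaled without mitochondrially encoded transcripts. With the mesenchymal mean as a covariate, a mean that includes both genes, the changes of COL1A1 and DCN were 0.31 and 0.82.

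Calcified bicuspid cells with XCT790 (n = 12) set against healthy cells gave MMP1 the largest rise, at 3089 ± 1889.5 against 68.7 ± 60.6 FPKM (SD, 6.34 ± 1.10, adjusted p = 8.00e-06). LAMP3 (4.49 ± 0.36), PSAT1 (4.21 ± 0.27), TRIB3 (3.95 ± 0.21), BEX2 (3.85 ± 0.39), PHGDH (3.76 ± 0.38), ASNS (3.73 ± 0.26), GDF15 (3.64 ± 0.34), CYP1A1 (3.57 ± 0.52) and CHAC1 (3.48 ± 0.24) rose as well. COL1A1 (−5.95 ± 1.39), COL1A2 (−5.90 ± 1.16), COL3A1 (−5.51 ± 0.70), DCN (−5.08 ± 1.10), CXCL6 (−5.04 ± 0.60), CADM3 (−4.70 ± 0.79), IGFBP5 (−4.40 ± 0.50), ITGBL1 (−4.25 ± 0.61) and PDGFRA (−4.19 ± 0.68) were among the lowest relative to healthy cells. By limma 6629 genes passed, 4337 higher and 2292 lower. The share of higher genes was 65.4%, but 48.5% with a median-of-ratios size factor and 51.2% without mitochondrially encoded transcripts, which moved the median of all genes from 0.139 to 0.005 and 0.035. With the mesenchymal mean as a covariate 3661 genes passed, and the changes of COL1A1, COL1A2 and DCN, which are part of that mean, were 1.02, 0.19 and 0.63.

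In both treated groups the integrated stress response and cell cycle lists stood apart from healthy cells: 25 and 24 of 26 stress genes were higher (25 each adjusted over the list alone; estimated-correlation adjusted p = 0.011 each), and 24 of 30 cycle genes lower in each (25 and 26 adjusted over the list alone; 0.012 and 0.011). Mesenchymal and interstitial cell genes were lower in 16 and 18 of 23 (18 each adjusted over the list alone), with median changes of −2.07 and −2.19 (camera adjusted p = 4.1e-08 and 9.9e-10, and adjusted p = 0.16 and 0.11 with an estimated correlation). Endothelial identity genes split in treated tricuspid cells, 3 higher and 6 lower of 29 (3 and 6 adjusted over the list alone; camera adjusted p = 0.037, and adjusted p = 0.68 with an estimated correlation). In treated bicuspid cells 5 were higher and 6 lower (5 and 6 adjusted over the list alone; camera adjusted p = 0.58), where the list's median was 0.22 but its mean −0.08 and the tested direction down, with LYVE1 among those lower (−3.43 ± 0.67).

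**Figure D4:**
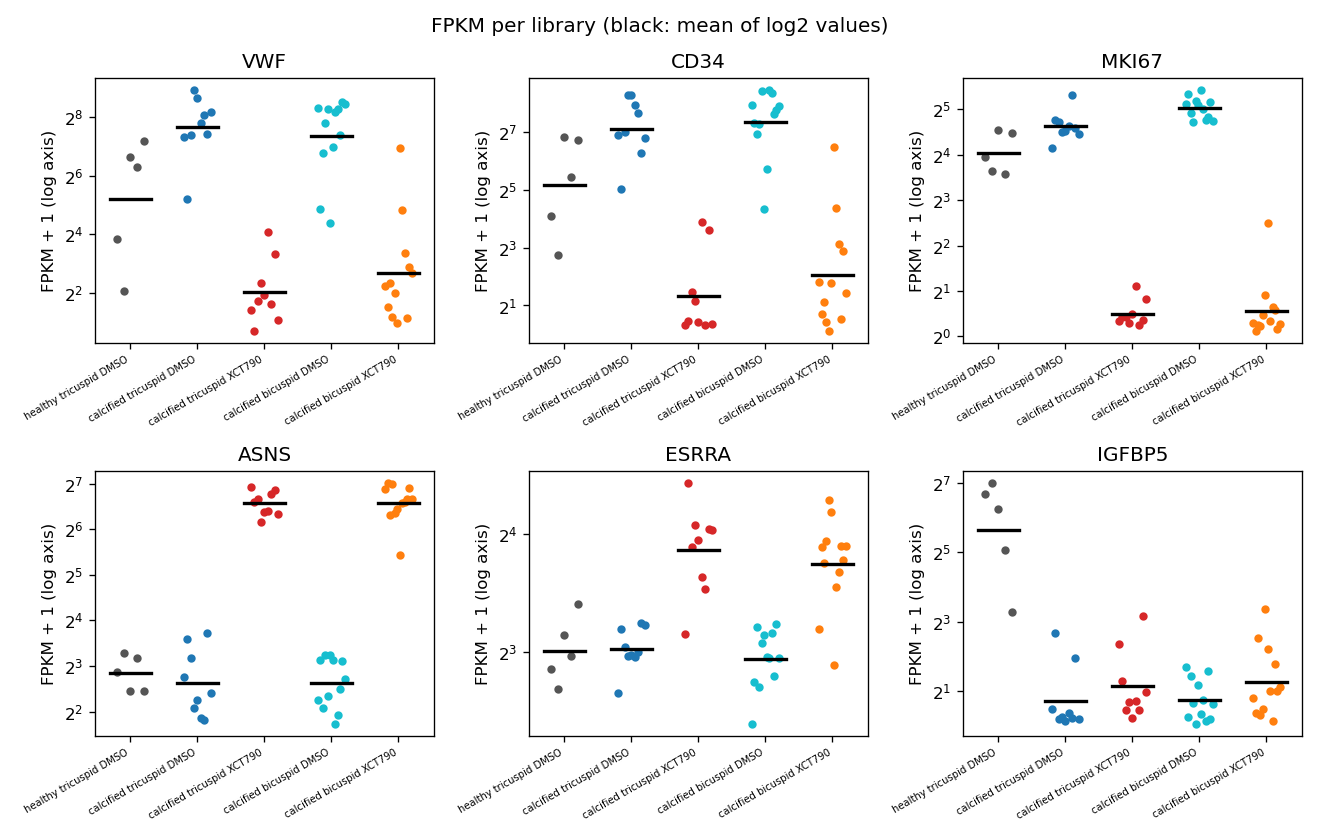
FPKM + 1 on a log axis (y) in each of the 47 libraries for 6 genes, by group (x), with 1 point per library and a bar at the group mean of log2(FPKM + 1). VWF and CD34 are highest in calcified DMSO cells, MKI67 is lowest with XCT790, ASNS and ESRRA are highest with XCT790, and IGFBP5 is highest in healthy cells.

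Finally, the drug change was compared with the disease change, to ask whether XCT790 moved calcified cells back. Disease and drug changes taken from separate replicate numbers correlated negatively across 13837 genes, which are not independent replicates, with a median r over 100 random divisions of the numbers of −0.25 (range −0.309 to −0.147) in tricuspid and −0.265 (−0.309 to −0.192) in bicuspid cells. Opposite signs were found for 53% and 55.1% of the genes: 47.9% and 50.9% of those higher in disease, and 61.3% and 61.4% of those lower. The median drug change over all genes was above 0 (0.085 and 0.043). By itself this lowers the share for genes higher in disease and raises that for lower ones. The gap between these shares therefore does not show that lowered genes were moved back more. By replicate number, the covariance of its own drug change with the disease change of the others was below 0 in 8 of 9 tricuspid numbers (mean −0.088, exact two-sided sign-flip permutation test p = 0.00781, smallest possible 0.00391) and in 11 of 12 bicuspid numbers (mean −0.095, p = 0.000977 by the permutation of all sign flips, smallest possible 0.000488). These p-values hold the 5 healthy libraries fixed, so their spread is not covered. Each number was also set against nearly the same disease change. The p-values therefore measure how steadily the drug changes of the numbers share a sign against it. They do not test whether the disease and drug changes lie opposite beyond a chance alignment. With 1 healthy library left out the mean covariance ranged from −0.11 to −0.066 and from −0.117 to −0.074. With all libraries, where both changes share the calcified DMSO libraries, r was −0.295 and −0.297. Unchanged groups simulated with that sharing gave −0.402 and −0.309, with covariances of −0.022 and −0.013 against −0.101 and −0.104 observed, a difference of −0.078 and −0.091. Genes were drawn independently in these simulations, while real genes vary together. The differences alone therefore do not show a reversal beyond the sharing.

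Among genes called in the disease comparison of the other replicate numbers, the median share with the opposite sign under the drug was 54.7% in tricuspid cells (16 of 100 divisions, those that called at least 10 genes) and 64.9% in bicuspid cells (56 of 100). By direction it was 63.4% and 70.3% for the higher and 48.5% and 57.4% for the lower genes. VWF went beyond its healthy level: it changed by 2.45 with tricuspid disease and by −5.64 with XCT790, and treated cells then lay below healthy ones (−3.19 ± 0.80, adjusted p = 0.000927). IGFBP5 stayed lower than in healthy cells with the drug, at 1.83 ± 2.56 FPKM. After treatment 452 of the 951 and 1030 of the 2317 higher genes no longer passed against healthy cells, 402 and 1077 still passed on the same side, and 97 and 210 passed on the other side. Of the 436 and 1019 lower genes, 161 and 405 no longer passed, 255 and 569 were still lower, and 20 and 45 were higher. These calls share the healthy libraries with the disease comparison, which favours the same side, and a gene that no longer passed is not shown to be at its healthy level.

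The authors' deposited table marks 1161 genes for the calcified tricuspid and 3130 for the calcified bicuspid disease comparison, and 7744 and 7739 for XCT790 in tricuspid and bicuspid cells. Among the genes tested here, the authors' deposited table marks 1113, 2929, 7217 and 7250, of which 809, 2176, 6465 and 6841 passed here as well. Lists drawn independently would share 112, 706, 3765 and 3844.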

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

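The tests of normalization, of the respiratory chain list and of interstitial outgrowth, and the covariates for the mesenchymal mean and depth, were chosen after the results were seen.

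Of 29 endothelial identity genes 11 in calcified tricuspid and 24 in calcified bicuspid cells were called higher than in healthy cells, and of 23 mesenchymal genes 2 and 7 lower, with none called the other way. In tricuspid cells 5 endothelial genes were higher and 4 mesenchymal genes lower with quantile normalization. With a median-of-ratios size factor these counts were 7 and 5. With an estimated correlation neither list was called (adjusted p = 0.36 for each in tricuspid and 0.43 in bicuspid cells), and the tricuspid calls rest on the fit of all groups (2 genes in a fit of only these groups). A different share of interstitial cells in the cultures may account for part of it. The slope on the mesenchymal markers within calcified DMSO libraries left 0.69 of the change of the called genes in tricuspid cells (bootstrap range 0.54 to 0.88) and 0.64 in bicuspid cells (0.46 to 0.85), so cell share and disease cannot be told apart, because the markers differ between the groups themselves. The bootstrap resampled only calcified DMSO libraries and held the observed changes from healthy cells fixed. Its slope also lacked the term for anatomy used for 0.69 and 0.64. The ranges may therefore be too narrow. With the marker mean as a covariate 81 genes passed in tricuspid cells, all 81 of them called before, and 836 in bicuspid cells, 794 of them called before, with HAPLN1 (−3.08 before) and IGFBP5 (−4.92 before) at −2.96 and −4.34 in bicuspid cells.

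Mitochondrially encoded transcripts fell with XCT790. Normalization to the total is argued against, since a median-of-ratios size factor, which follows the typical gene and not the total, left medians of −3.54 in tricuspid and −2.67 in bicuspid cells. A joint fall of all respiratory chain transcripts is argued against too, as the nuclear-encoded oxidative phosphorylation list had medians of −0.12 and −0.08. On the scale rescaled to all other transcripts these were −0.27 and −0.26 (SD over 74 genes 0.22 and 0.20), with 32 and 36 genes called lower and 1 higher in each. The lowest nuclear-encoded gene there was at −0.80 and −0.75, and the mitochondrially encoded transcript that fell least at −2.42 and −1.64. A smaller fall of nuclear-encoded genes stays open. Depth as the whole cause is argued against in tricuspid cells, where the median with depth as a covariate was −1.63 and 9 of 13 members still passed as lower. In bicuspid cells that median was −0.53 with 1 of 13 still lower, so depth and drug cannot be told apart there. Treated libraries were deeper in 8 of 9 tricuspid and 12 of 12 bicuspid pairs, so this alone does not set bicuspid cells apart. The shallowest treated bicuspid libraries were replicates 5, 6 and 8 (4.21, 5.46 and 5.5 in the depth units above). Their mitochondrial shares were 25.9%, 17.3% and 18.6%, above those of their DMSO partners. The deeper treated bicuspid libraries had at most 9.37%. The shallowest treated tricuspid library, replicate 7 (5.86), also had the highest treated share there (8.12%), but its partner had 13.1%. An effect of the drug on mitochondrial transcripts may also contribute.

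Endothelial identity genes fell with XCT790 in 9 of 9 tricuspid pairs (mean −1.68 ± 0.47) and 12 of 12 bicuspid pairs (−1.51 ± 0.59, range −2.21 to −0.04, so at least 1 pair moved little). Outgrowth of interstitial cells would raise their markers, but the mesenchymal list had medians of −0.61 and −0.51. That list holds collagen genes such as COL3A1, and most extracellular matrix genes fell with XCT790. A fall of such transcripts within cells could hide a larger share of interstitial cells, so these medians cannot decide on outgrowth. A loss of endothelial expression within the cells may explain the fall and was not tested.

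Some lists differed in their drug change between both kinds of calcified valve by camera on the interaction, though no single gene did. The difference, bicuspid minus tricuspid, had a median of 0.81 for mitochondrially encoded transcripts (camera adjusted p = 1.6e-05), −0.45 for NF-kB and inflammatory genes (1.6e-05), −0.20 for the cell cycle (4.9e-05), 0.09 for ribosomal proteins (1.6e-06), 0.10 for cholesterol synthesis (0.023), 0.04 for oxidative phosphorylation (0.032) and 0.14 for endothelial identity (0.049). With an estimated correlation each had an adjusted p of 0.93, and with the replicate block endothelial identity was not called (adjusted p = 0.071). Nor were ribosomal proteins (0.11), oxidative phosphorylation (0.14) and endothelial identity (0.14) with quantile normalization, or cholesterol synthesis (0.81) and endothelial identity (0.053) with library weights. The sign for ribosomal proteins was the other way with quantile normalization (−0.06) and TPM (−0.01), and that for oxidative phosphorylation with TPM (−0.06). The difference in mitochondrial share itself was 4.5 percentage points (permutation p = 0.16, two-sided).

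Dixon's ratio, the gap of the farthest library to its neighbour over the group's range, was above its critical value in 52 of 399 tests of the 3 groups with at most 10 libraries; chance gives about 1 in 20. In calcified tricuspid DMSO cells 19 were at the low end, 17 of them from the same library: SOX7 (0.772), CYYR1 (0.769), TIE1 (0.73), ERG (0.713), E2F3 (0.694), EMCN (0.654), BMP6 (0.649), CAVIN2 (0.645), FLRT2 (0.623), CLDN5 (0.58), VWF (0.571), SMAD1 (0.564), POSTN (0.552), GDF15 (0.551), MGP (0.534), ESRRA (0.519), CLU (0.512), CTNNBL1 (0.498) and NOTCH1 (0.498). At the high end were IL1B (0.613), C3 (0.592), HSD11B1 (0.592), MELTF-AS1 (0.55), AREG (0.508) and KIF20A (0.504). With XCT790 in these cells the low end held BMP6 (0.676), ERG (0.665), CAVIN2 (0.631), TIE1 (0.6), NID1 (0.578), XXYLT1-AS2 (0.522) and CYYR1 (0.508), and the high end FABP4 (0.753), AURKB (0.695), GJA4 (0.66), HAPLN1 (0.622), C3 (0.602), LINC01985 (0.596), SELP (0.582), RRM2 (0.575), TWIST2 (0.571), TLNRD1 (0.568), RUNX2 (0.563), LIF (0.546), SOX18 (0.527), BIRC5 (0.512), TNFRSF11B (0.512) and IL1B (0.504). In healthy cells they were CIB2 (0.752), the mitochondrial share (0.742) and CLGN (0.737) at the high end and SOX9 (0.713) at the low end.

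Other splits of the same libraries were fitted for each count of genes, 100 each with the real one included. In the calcified tricuspid disease comparison 2 splits gave as many genes (real 1387, highest other 1539), and in the bicuspid one 1, the real one (3336 against 3088). The real split was also the only 1 of its size for XCT790 in tricuspid (7219 against 5489; 6026 among splits within pairs) and bicuspid cells (7337 against 1137; 6210 within pairs), and for the treated groups against healthy cells (6824 against 4247, and 6629 against 5421). Chance can be excluded at 1 of 100 for these counts except both disease counts. For the bicuspid disease count no other split drawn gave as many genes, but the highest lay close to it. The bicuspid count was 991 without healthy replicate 1, 836 with the mesenchymal covariate and 730 by the Wilcoxon test. With the replicate block it was 13, in a fit that rests on the numbers present in both groups. Chance is therefore not firmly excluded for it. For the tricuspid one chance is not excluded. In the fit of all groups 2 of 100 splits, the real one included, gave as many genes, and the other split gave more. The count was 39 without healthy replicate 1, 2 in a fit of only these groups and 0 by the Wilcoxon test. All these splits treat libraries as independent, which the labels do not state. For both calcified groups against each other and for the interaction, where the real count was 0, all 100 splits give as many by construction (highest other 13 and 1), so the splits decide nothing.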

How the results depend on the processing

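The covariates, the rescaling without mitochondrially encoded transcripts and the block with an estimated correlation were chosen after the data were seen. The drug comparisons kept their counts within 1.5 times under every setting (leaving out 1 library, 6918 to 7307 in tricuspid and 7043 to 7598 in bicuspid cells), as did calcified tricuspid XCT790 against healthy cells (6055 to 6885); calcified bicuspid XCT790 against healthy cells (5677 to 6923) moved only with the mesenchymal covariate (3661). With depth as a covariate 5585 and 5155 genes passed in the drug comparisons. The replicate block, which pairs libraries in the drug comparisons, changed no call of a named gene there except with quantile normalization, where NOTCH1 in tricuspid cells passed (−0.38, limma adjusted p = 0.0309), as it did with the mesenchymal covariate (−0.54, 0.0433). In the disease comparisons libraries with the same number correlated with r −0.33 to 0.6 (median 0.14, other numbers −0.03) in tricuspid cells. In bicuspid cells r was 0 to 0.22 (median 0.16, other numbers −0.04). On the third component (4.4% of the variance) replicate 0 of all 5 groups lay between −39.7 and −23.31. The lowest other libraries were healthy replicate 1 (−22.52) and calcified bicuspid DMSO replicate 2 (−15.99). A batch that goes with the number is therefore not excluded. With the block 0 and 13 genes passed in the disease comparisons, and 5051 and 4810 for the treated groups against healthy cells. Healthy cells have only replicates 0, 1, 2, 3 and 4, so calcified libraries with higher numbers add nothing to these block fits. The lower counts can therefore come from the fewer libraries used and are not a sign of a batch by themselves. The calcified tricuspid disease count (1387) was 916 with a mean FPKM of at least 5, where fewer genes are tested, 3210 with library weights, 81 with the mesenchymal covariate, 2 in a fit of only these groups and 0 by the Wilcoxon rank-sum test. It ranged from 39 to 2909 when 1 library was left out: 60, 39, 2868, 296 and 2284 without healthy replicates 0, 1, 2, 3 and 4, and 2909, 740, 800, 748, 907 and 788 without calcified tricuspid DMSO replicates 1, 3, 4, 5, 6 and 8. The bicuspid disease count (3336) was 2216 with a mean FPKM of at least 5, 836 with the mesenchymal covariate and 730 by the Wilcoxon test, and ranged from 991 to 4487, being 1561, 991 and 2182 without healthy replicates 0, 1 and 3. Both calcified groups against each other and the interaction gave 0 genes without any library. Of the values of named genes under other settings, 159 of 563 in the tricuspid and 84 of 562 in the bicuspid disease comparison kept their direction but no longer passed (38 of 38 and 36 of 38 genes no longer passed or changed sign under at least 1 setting; 35 of 38 and 13 of 38 when 1 library was left out, with 135 of 532 and 28 of 646 values no longer passing), against 2 of 300 in each of the treated groups against healthy cells and none in the drug comparisons. The number of lists called fell with an estimated correlation from 16 to 0 and from 17 to 0 in the disease comparisons, from 5 to 0 between calcified groups, from 19 to 4 and 18 to 5 in the drug comparisons (0 and 1 with the block as well), from 23 to 7 and 24 to 4 against healthy cells, and from 7 to 0 for the interaction (0 with the block as well). With fry it was 6 and 10 in the disease comparisons, 0 between calcified groups, 28 and 29 in the drug comparisons and 0 for the interaction, with quantile normalization 9 and 9 in the disease comparisons, and with library weights 3 between calcified groups. ESRRA, near 0, changed sign in the tricuspid disease comparison with quantile normalization (−0.08), the size factor (−0.07) and the block (−0.05), and ranged from −0.07 to 0.12 when 1 library was left out (−0.02, −0.07, 0, −0.01 and −0.01 without healthy replicates 0 and 1 and calcified replicates 1, 7 and 8). In the bicuspid one it ranged from −0.15 to 0.03 (without healthy replicate 4), and its interaction changed sign with quantile normalization (0.02, also with the block), the size factor (0.01) and library weights (0.04), ranging from −0.12 to 0.05 (0.02, 0.04, 0.02 and 0.05 without calcified tricuspid DMSO replicate 0, XCT790 replicate 1 and calcified bicuspid XCT790 replicates 0 and 6). COL1A1 (0.31 and 1.02), DCN (0.82 and 0.63) and, in bicuspid cells, COL1A2 (0.19) changed sign against healthy cells with the mesenchymal covariate, of which they are part. The correlation of drug and disease change was −0.346 in bicuspid cells (range −0.494 to −0.12) on genes called in the disease comparison of the other libraries, a median of 596 genes in the 56 of 100 divisions that called at least 10, and −0.221 in tricuspid cells (−0.523 to −0.079; 216 genes, 16 divisions). On all genes and divisions it ranged from −0.26 to −0.219 and from −0.273 to −0.239 when 1 healthy library was left out. Apart from the stricter filter, the cause of these shifts was not tested. Depth is approximate and limits genes with few reads.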

Other observations

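The test of ERRα targets was chosen after the drug results were seen. Since XCT790 is an inverse agonist of ERRα, a hypothesis was that it lowers the transcripts of ERRα targets together. Of 18 measured genes of the ERRα pathway list, 7 rose and 2 fell in calcified tricuspid cells (7 and 2 adjusted over the list alone; camera adjusted p = 0.41), and 6 rose and 2 fell in bicuspid cells (6 and 2 adjusted over the list alone; camera adjusted p = 0.34). A joint fall of the genes of this list is therefore argued against at the level of transcripts, as only 2 members were lower in each. Transcripts may not follow the activity of the receptor, and ERRα targets outside the list are not covered. The oxidative phosphorylation and fatty acid oxidation lists below had more lower than higher genes in the main fit. A smaller fall of ERRα targets among energy genes therefore stays open.

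Other metabolic and stress lists moved both ways. Of 20 p53 response and senescence genes 11 rose and 4 fell in tricuspid (camera adjusted p = 0.063) and in bicuspid cells (0.082), and of 20 hypoxia genes 8 and 9 rose and 5 fell in each (0.22 and 0.13). Unfolded protein response genes split 11 to 10 and 10 to 10 of 21. Among 21 NOTCH pathway genes 4 rose and 8 fell in tricuspid cells (camera adjusted p = 0.16, with a median of 0.05 but a mean of −0.25), and 3 rose and 10 fell in bicuspid cells (0.082). Oxidative phosphorylation had 2 genes higher and 13 lower of 74 in tricuspid cells and 6 and 10 in bicuspid cells (camera adjusted p = 0.050 and 0.17). Rescaled without mitochondrially encoded transcripts these counts were 1 and 32, and 1 and 36, and with TPM 8 and 8, and 5 and 16. Fatty acid oxidation had 5 and 11 of 26 in tricuspid and 5 and 12 in bicuspid cells (0.058 and 0.15). In tricuspid cells both lists passed with the replicate block (0.022 and 0.032) and with quantile normalization (0.045 and 0.047), and oxidative phosphorylation with a pseudocount of 0.1 (0.049), but not with an estimated correlation (0.73 and 0.37, and 0.63 and 0.28 with the block as well).

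Per pair, the mean change of the integrated stress response was 2.54 ± 0.26 in tricuspid cells (SD, 9 of 9 pairs higher) and 2.45 ± 0.44 in bicuspid cells (12 of 12), and that of the cell cycle −2.16 ± 0.23 and −2.37 ± 0.27. In 4 relations of the mitochondrial change with these lists across pairs, none passed after adjustment. The largest was with the cell cycle in bicuspid cells (Pearson's r = 0.66, permutation p = 0.021, adjusted p = 0.084; Spearman's rho 0.56, p = 0.064; r = 0.49 without the 2 pairs farthest from the median). The relation with the stress response in tricuspid cells went from r = −0.24 to 0.76 without the 2 farthest pairs, that in bicuspid cells from −0.47 to 0.14, and that with the cell cycle in tricuspid cells from −0.17 to −0.33.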
